A study of Mus musculus with 8 samples.

How the data were processed

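Total RNA from microdissected neocortical tissue of 8 mouse pups at postnatal day 2 was hybridised to Affymetrix mouse gene arrays, 1 array per pup, which gave 4 control and 4 mutant arrays. Per the labels, the control pups carried 1 floxed allele of Bcl11a with Cre recombinase expressed from the Emx1 locus, and the mutant pups carried the same Cre with both alleles floxed. The control animals are therefore heterozygous where Cre acts, and each comparison sets loss of both alleles against loss of 1. Per the labels, BRB-ArrayTools was used by the submitters. The background correction, the normalization between arrays, the summarisation of probes and the base of the logarithm are not given in the sources used here. The deposited values run from 2.03 to 13.8 with array medians between 4.83 and 4.91, and were taken as log2 expression already normalized between arrays. If the base were another, the tests would be the same and the fold changes would differ.

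The value table held 35556 probe sets. The platform's annotation table paired 21789 of them with 1 gene symbol and 1621 with several, and left 12146 unnamed. Of the probe sets with 1 symbol, 21698 were matched by Entrez Gene identifier to the gene table of assembly GRCm38.p6, which was used for names alone, and 0 symbols needed updating. The array annotation names no genome build, so no genome positions are given. Probe sets with 1 symbol were kept. For the 999 genes with more than 1 such probe set the brightest over the 8 arrays was taken, which left 19938 genes, with no filter on dim genes. A gene with no such probe set was not analysed here.

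Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3, with a linear model on genotype alone, moderated variances (6.91 prior degrees of freedom) and a two-sided moderated test for each gene. Adjusted p-values are Benjamini-Hochberg values over all 19938 genes unless stated otherwise, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. Differences are mutant minus control on the log2 scale, with the model's standard error (SE), and means are given with their SD over 4 pups. An exact two-sided permutation test over the 70 ways to choose 4 of 8 arrays cannot give a p under 0.0286. The number of arrays limits the precision, and the median SE of the log2 difference was 0.0766.

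Gene lists for cortical layers, areal patterning, cell death, guidance, migration, receptors, channels, cell types and RNA quality were written before the data were examined, as were the test, the list of alternative settings and the rule for naming genes. The 33 lists were tested with limma's camera against all other genes (preset correlation between genes of 0.01) with Benjamini-Hochberg adjustment over the lists, beside camera with a correlation estimated for each list and fry, which tests whether a list's genes move one way on balance. By the rule, the text names Bcl11a, Bcl6 and Sema3c, the 12 largest rises and the 12 largest falls among changed genes whose control and mutant values did not overlap, and up to 4 members of each list, those past the threshold taken by size of change. Predicted genes without an official name were not named. This gave 86 genes. Another 49 genes were named only after their values had been seen, where few members of a list had changed or in the closing observations: in the report these are Id2, Igfbp4, Ntsr1, Ephb1, Rnd2, Efnb1, Efna5, Robo2, Sema5a, Plxnc1, Plxna1, Ret, Fgfr1, Ntrk2, Gria4, Grid1, Kcnh3, Kcnh5, Pcdh18, Rgs2 and Rgs4. Bcl11b, Fezf2, Per2, Per3, Bhlhe41, Arntl, Lhx6, Gad1 and Dlx6, which did not pass, were also named after their values had been seen.

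The sex of each pup was inferred from Xist and from Y-linked genes. In the 3 arrays with high Xist, 3 Y-linked genes read between 3.33 and 4.31. The upper of these values was taken as an empirical floor below which a reading may be background. The mean of 6290 genes (31.55%) lay at or below it.

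The procedure was tested on simulated data for the same 19938 genes with 200 genes changed. It recovered 66 of 67 genes changed by 0.5 on the log2 scale, 67 of 67 changed by 1 and 66 of 66 changed by 2, and 7.53% of its calls were genes that had not been changed. Of the 33 lists, both that were shifted by 0.3 were recovered by each of the 3 list tests, and camera called 0 others with either correlation while fry called 3. The simulated noise was independent between genes, so false calls of lists with correlated genes were not tested. In the real arrays the estimated correlation reached 0.253, for the ribosomal list. Alternatives covered the normalization between arrays, filters on the dimmest 30% and 50% of genes, the treatment of several probe sets, array weights, variance estimation, thresholds, the replicate number as a block, and the omission of each array in turn. Tests on all probe sets and with inferred sex as a covariate were added after seeing the data.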

Results

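Expression was measured in layers II to IV of the neocortex of newborn mice in which Bcl11a, a zinc finger transcription factor of cortical projection neurons, had been deleted in the Emx1 lineage, which gives rise to the excitatory neurons and much of the glia of the cortex. The tissue was cut from sections with a laser at postnatal day 2, from 4 control pups with 1 floxed allele and 4 mutant pups with 2. The series title names Bcl11a and Bcl6 as parts of a pathway that governs the developmental death of projection neurons, and the comparison asks which genes differ in the mutant layers. Values are log2 intensities of 1 array per pup, and array medians lay between 4.83 and 4.91. Correlations across genes were 0.994 to 0.997 between arrays of the same genotype and 0.991 to 0.995 between genotypes, and genes are not independent replicates. Principal component 1, with 38.4% of the variance, separated the genotypes, with controls from -19.1 to -7.61 and mutants from 9.91 to 14.51. On component 2 (17.4%), control 1 lay apart at -16.59, and it had the lowest array weight, 0.556. Xist was high in 2 of 4 controls and 1 of 4 mutants (at least 8.89, against at most 3.81 elsewhere), and the 3 Y-linked genes were low in the same arrays, so the pups were of both sexes in each group.

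Bcl11a itself fell in the mutant tissue from 10.45 ± 0.13 to 8.63 ± 0.21 (SD, n = 4), a drop of 3.52-fold with a 95% interval of 3.03 to 4.10. The log2 difference was -1.82 (SE 0.10, adjusted p = 4.9e-07). The control mean stood at percentile 98.53 of all genes and the mutant mean at percentile 89.42, so that signal remained in the mutant. Bcl6, a transcriptional repressor, fell by 1.82 on the log2 scale (SE 0.12), from 7.88 ± 0.23 to 6.06 ± 0.21 (SD, n = 4), a 3.53-fold drop with an adjusted p of 1.65e-06. Sema3c, a secreted semaphorin, rose from 7.61 ± 0.05 to 9.08 ± 0.03 (SD, n = 4), a 2.76-fold increase (log2 difference 1.47, SE 0.06, adjusted p = 3.35e-08). All 4 mutant values lay outside the control range for each of these genes, and the exact two-sided permutation p was 0.0286 for each, the smallest that 4 arrays against 4 can give. The controls keep 1 intact allele of Bcl11a, and whether its probe set lies in the deleted part was not analysed here.

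**Figure D1:**
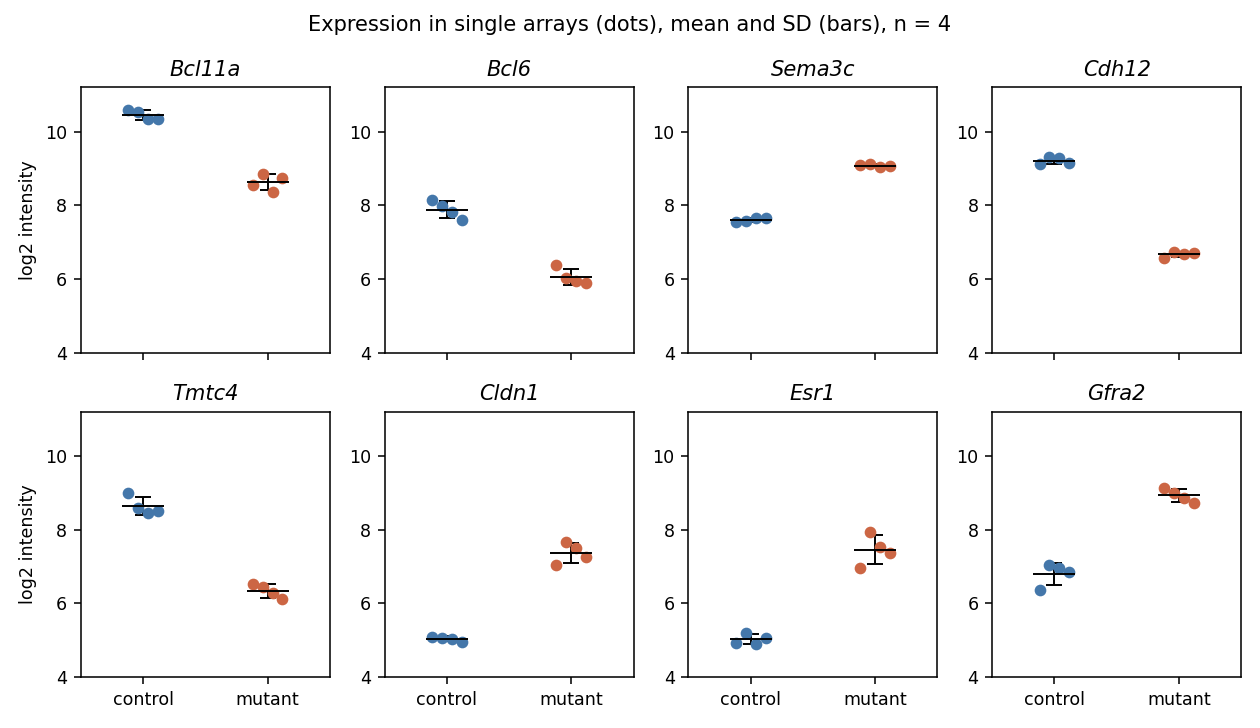
Log2 intensity of 8 genes in each of 4 control and 4 mutant pups (dots), with the group mean and SD (bars). For Bcl11a the controls average 10.45 and the mutants 8.63. The 2 genotypes do not overlap for any gene plotted, which was a condition for naming Cdh12, Tmtc4, Cldn1, Esr1 and Gfra2 among the largest changes.

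Across the genome, 827 of 19938 genes (4.15%) differed between mutant and control layers, 470 higher and 357 lower in the mutant. Most of these changes were moderate: the median absolute log2 difference of the changed genes was 0.47, and 41 genes rose and 32 fell by at least 2-fold. The largest fall was that of Cdh12, a classical cadherin, from 9.21 ± 0.09 to 6.68 ± 0.07 (SD, n = 4), a 5.79-fold drop with an adjusted p of 3.02e-10. The largest rise was that of Esr1, the estrogen receptor alpha, from 5.03 ± 0.13 to 7.45 ± 0.40, which is 5.38-fold (SD, n = 4, adjusted p = 1.13e-06). Of all genes, 9.25% had control and mutant values that did not overlap, against 2.86% by chance for 4 against 4.

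Tmtc4, a mannosyltransferase of the endoplasmic reticulum, fell 4.89-fold and Igfbp5, a binding protein of insulin-like growth factors, fell 3.84-fold (adjusted p = 2.77e-07 and 1.09e-06). Nr4a2, an orphan nuclear receptor, fell 4.45-fold, but its control values varied widely (6.83 ± 0.98, SD, n = 4, adjusted p = 0.00212). Trhde, the ectoenzyme that degrades thyrotropin-releasing hormone, fell 3.50-fold, and the gene of neuropeptide Y, Npy, fell 3.09-fold. The teneurin Tenm3 fell 2.81-fold, Atp10b 2.73-fold, and the clock repressor Nr1d1 2.67-fold. Trpa1, a cation channel gene, fell from 5.84 ± 0.16 to 4.02 ± 0.30 (SD, n = 4), which lies below the empirical floor of 4.31, so the drop was at least 2.88-fold. For these 8 genes other than Nr4a2 the adjusted p was at most 9.39e-04.

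Cldn1, a tight junction protein, rose 5.0-fold from 5.05 ± 0.06 to 7.37 ± 0.27 (SD, n = 4, adjusted p = 1.56e-07). Gfra2, the receptor of neurturin, rose 4.38-fold and Rspo2, a secreted enhancer of Wnt signalling, rose 4.22-fold (adjusted p = 1.09e-06 and 4.69e-07). Npnt, an extracellular matrix protein that binds integrins, rose 3.62-fold, with an adjusted p of 0.0056, and Itga9, an integrin subunit, rose 2.99-fold. Receptors of neuropeptides were also among them: Avpr1a, a vasopressin receptor, rose 3.51-fold and Sstr2, a somatostatin receptor, rose 3.0-fold. Olfm3 rose 3.52-fold, the transcriptional repressor Bhlhe40 2.82-fold and Wscd1 2.68-fold. With each gene's variance taken from its own arrays without moderation, 249 genes passed, Bcl11a, Bcl6 and Sema3c among them, while 68 of the 135 named genes no longer did. With an intensity trend and robust variances, 8 named genes lost the call, in the report Nr4a2, Npnt, Ldb2, Cdh13, Pcdh9 and Plxnc1 (adjusted p = 0.0705, 0.115, 0.116, 0.160, 0.0683 and 0.109).

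**Figure D2:**
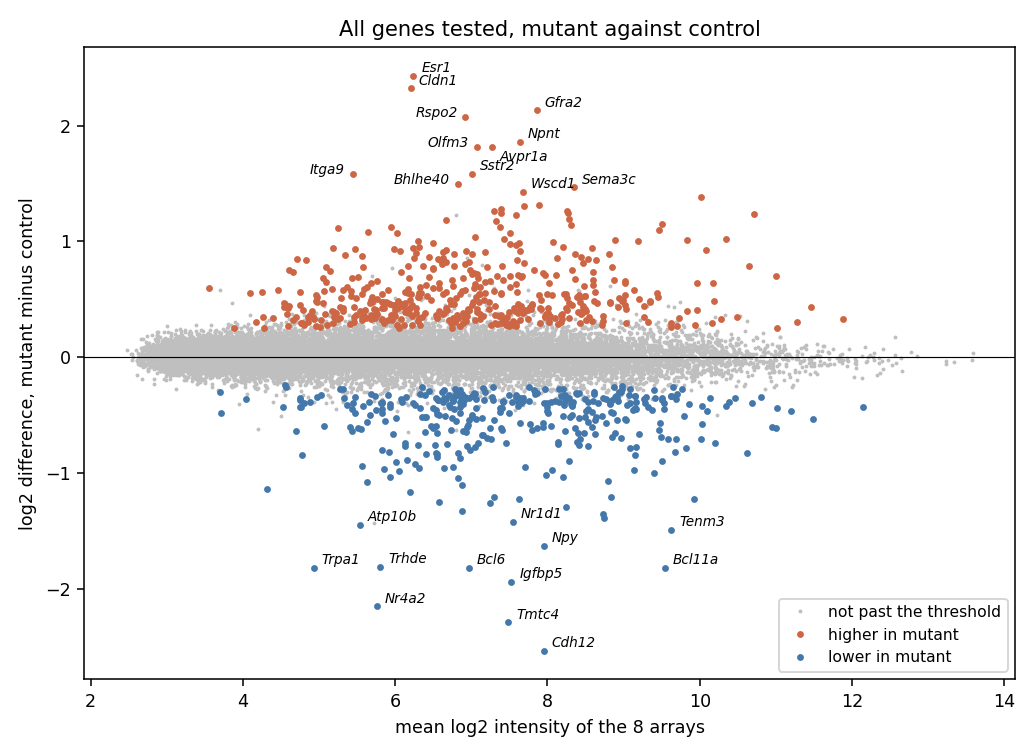
Mean log2 intensity of the 8 arrays (horizontal axis) and log2 difference, mutant minus control (vertical axis), for all 19938 genes tested. Coloured dots mark the 470 genes that were higher and the 357 that were lower in the mutant at an adjusted p under 0.05; labels name Bcl11a, Bcl6, Sema3c and the 12 largest changes in each direction.

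Of the genes of upper-layer projection neurons more fell than rose. Of 31 measured, 12 fell, 3 rose and 16 did not pass, and adjusted over the list alone 14 fell and 6 rose. Tmtc4, Cux2 (8.90 ± 0.05 to 7.60 ± 0.16, SD, n = 4) and Mdga1 had the largest falls, with log2 differences of -2.29, -1.29 and -1.07; Cux2 encodes a homeodomain factor of layers II to IV and Mdga1 an adhesion molecule. The members that rose were the LIM-only gene Lmo4 (1.10), Id2, an inhibitor of basic helix-loop-helix factors (1.02), and Cdh13 (1.02). Of the genes of deep-layer projection neurons, those of layers V and VI, more rose than fell: of 27 measured, 7 rose, 3 fell and 17 did not pass, and adjusted over the list alone 9 rose and 3 fell. Ldb2 (1.38), the neuropeptide gene Grp (1.26) and Crim1 (1.07) rose, whereas Cntn6, a contactin (-1.26), Ntsr1, a neurotensin receptor used as a layer VI marker (-0.90), and the ephrin receptor gene Ephb1 (-0.77, and -0.40 with the mean of its probe sets) fell. The layer V regulators did not pass, with log2 differences of 0.05 for Bcl11b (adjusted p = 0.919) and 0.80 for Fezf2 (adjusted p = 0.105). As sets, the upper-layer list was lower (adjusted p = 4.26e-04) and the deep-layer list higher (adjusted p = 0.0114), each with an adjusted p = 0.329 with an estimated correlation. The call of Cdh13 was lost without mutant 2, 3 or 4 (adjusted p from 0.055 to 0.0707). In the same arrays the interneuron markers were lower by camera (median log2 difference -0.19), though not with an estimated correlation (adjusted p = 0.0802).

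**Figure D3:**
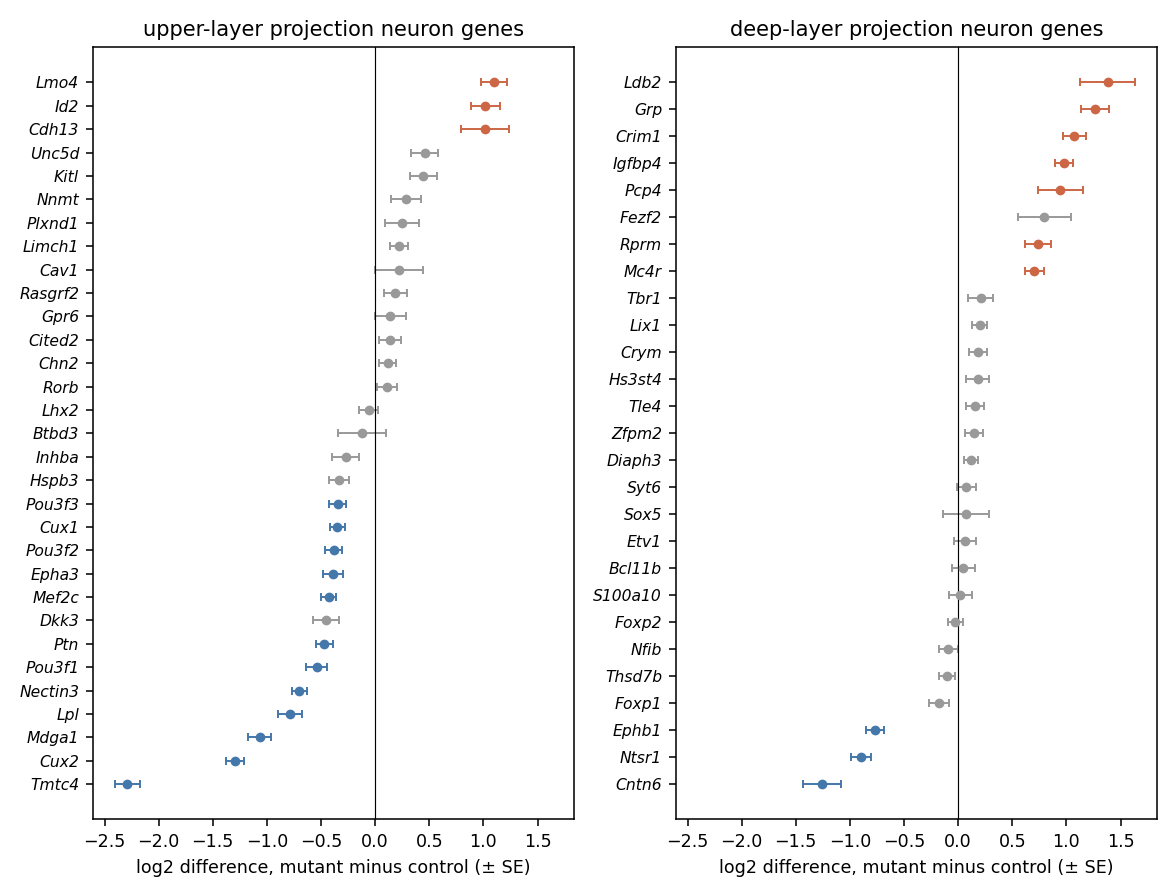
Log2 difference, mutant minus control, with its SE for each measured gene of the upper-layer (31 genes, left) and deep-layer (27 genes, right) lists. Blue and orange dots are genes that were lower or higher at an adjusted p under 0.05, and grey dots did not pass; 12 upper-layer genes fell and 7 deep-layer genes rose.

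Genes that pattern the cortex into areas changed in both directions, with 7 of 21 measured falling, 3 rising and 11 not passing, and 9 falling and 3 rising adjusted over the list alone. Tenm3 (-1.49), the LIM-only gene Lmo3 (-1.22) and the cadherin gene Cdh6 (-1.21) had the largest falls, and the 3 that rose were Lmo4, Id2 and Igfbp4 (0.97). The set was lower with an adjusted p of 0.0168 (adjusted p = 0.329 with an estimated correlation), and this call was lost without control 2 (adjusted p = 0.098), after quantile normalization (0.0563) and without the dimmest 50% of genes (0.185). The interneuron, vascular and meningeal lists were also lower by camera (medians of -0.19, -0.07 and -0.16), though not with an estimated correlation (adjusted p = 0.0802, 0.211 and 0.361). Of 25 classical cadherin and protocadherin genes, which encode adhesion molecules, 7 fell, 2 rose and 16 did not pass, and adjusted over the list alone 7 fell and 5 rose. Cdh12, Cdh6 and Pcdh9 (-0.77) fell, and Cdh13 and Pcdh18 (0.32) rose. This list did not pass as a set by camera (adjusted p = 0.0582) but was lower by fry (adjusted p = 0.00435), and its median of 0.02 and mean of -0.17 differ in sign. The calls of Pcdh9 and Cdh13 were lost without mutant 2, 3 or 4 (adjusted p from 0.0559 to 0.0719 for Pcdh9 and from 0.055 to 0.0707 for Cdh13), and that of Pcdh18 without mutant 1, 2 or 3 or control 2 or 4 (0.0507 to 0.0745). Among 12 subplate genes, Nr4a2 alone passed the test, both over all genes and adjusted over the list alone, and the set did not pass (adjusted p = 0.217).

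Of 37 pro-apoptotic genes, 2 rose, 0 fell and 35 did not pass, with the same counts adjusted over the list alone: Foxo1, a transcription factor (6.86 ± 0.33 to 7.51 ± 0.06, log2 difference 0.65, adjusted p = 0.00972), and Bid, a BH3-only protein (5.77 ± 0.05 to 6.13 ± 0.09, log2 difference 0.36, adjusted p = 0.00599; SD, n = 4). Of 22 anti-apoptotic genes, Bcl6 fell, Bcl2 rose (0.67, adjusted p = 0.00226) and 20 did not pass; adjusted over the list alone 2 rose and 1 fell. Of 27 targets of p53, 3 rose, 0 fell and 24 did not pass, and adjusted over the list alone 4 rose and 1 fell. The 3 were Sulf2, a heparan sulfate sulfatase (0.89), Trp53inp1 (0.50) and Rrm2b, a ribonucleotide reductase subunit (0.45). The pro-apoptotic (adjusted p = 0.210), anti-apoptotic (0.943) and p53 target (0.231) lists did not pass as sets by camera, while by fry the p53 target list was higher (adjusted p = 0.0426). The means of the pro-apoptotic and p53 target lists, which share 4 genes, were in each of the 4 mutants above those of every control. The same held for the deep-layer, glutamate receptor, GABA receptor and striatal lists. The medians of the pro-apoptotic list overlapped, with -0.0033 in mutant 4 and 0.0187 in control 1, relative to the control mean. Rrm2b lost its call without mutant 2 (adjusted p = 0.0628) or mutant 3 (0.0548). Without variance moderation Foxo1 (adjusted p = 0.1795), Bcl2 (0.0963), Trp53inp1 (0.133) and Rrm2b (0.177) lost the call, while Bcl6, Bid and Sulf2 kept it. Some members of these lists were not analysed here.

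Receptors of neurotrophic factors changed in both directions. Of 25 genes measured from the list written for such factors and receptors, 4 rose, 3 fell and 18 did not pass. Adjusted over the list alone 6 rose and 3 fell. The risers were 3 receptor subunits of the GDNF family, Gfra2 (2.13), Gfra1 (0.79) and Ret (0.35), and Fgfr1, a fibroblast growth factor receptor (0.34). Sorcs1, a sorting receptor (-1.02), Fgf13, kept as the list was written (-0.38), and Ntrk2, the receptor of BDNF (-0.37), fell. Whether Fgf13 acts as a neurotrophic factor was not tested. The set did not pass by camera (adjusted p = 0.880).

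Guidance genes also moved both ways. Of 31 semaphorin, plexin and neuropilin genes, 4 rose, 3 fell and 24 did not pass, and adjusted over the list alone 10 rose and 4 fell. Sema3c (1.47), Sema3d (0.84), Plxnc1 (0.84) and Sema5a (0.55) rose, while Sema3a (-1.03), Sema7a (-1.0) and Plxna1 (-0.45) fell. Of 39 other axon guidance genes, 5 rose, 6 fell and 28 did not pass, and adjusted over the list alone 10 rose and 8 fell. The secreted ligand Slit2 (1.31), its receptor Robo1 (0.92), the adhesion proteins Flrt3 (1.23) and Flrt2 (0.99), and the ephrin gene Efnb1 (0.45) rose. Among the 6 that fell were the ephrin gene Efna5 (-0.87), Ephb1 (-0.77, or -0.40 as the mean of its probe sets) and Robo2 (-0.35). With inferred sex as a covariate, 3 of these 39 genes fell and 6 rose, and 2 of the semaphorin, plexin and neuropilin genes rose. Neither list passed as a set by camera (adjusted p = 0.880 and 0.510). The call of Sema5a was lost without any 1 array other than control 1 or control 4 (adjusted p from 0.0689 to 0.149), and that of Plxnc1 without any 1 mutant (0.0505 to 0.0776).

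Of 28 genes of radial migration, 4 fell, 1 rose and 23 did not pass, with the same counts adjusted over the list alone. Those that fell were Vldlr, a receptor of reelin (8.78 ± 0.04 to 8.07 ± 0.05, log2 difference -0.71, SD, n = 4), the adhesion genes Nectin3 (-0.70) and Nectin1 (-0.54), and Reln itself (-0.57), while the small GTPase gene Rnd2 rose (0.42). The set was lower with an adjusted p of 9.34e-04 (adjusted p = 0.270 with an estimated correlation), and 22 of its 28 members had differences below 0. Reln is also a Cajal-Retzius marker, and in the same arrays camera called the interneuron, vascular and meningeal lists lower (medians of -0.19, -0.07 and -0.16), calls that were lost with an estimated correlation (adjusted p = 0.0802, 0.211 and 0.361). The call of Reln was lost without control 2, 3 or 4 or mutant 2 or 3 (adjusted p from 0.0702 to 0.102). Of 28 Notch pathway genes, Notch2 fell (-0.45), Hey2 rose (0.48) and 26 did not pass, against 4 rising and 1 falling adjusted over the list alone, and the set did not pass (adjusted p = 0.927). Hey2 lost its call without control 1 or 2 or mutant 2, 3 or 4 (adjusted p from 0.0534 to 0.114).

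Receptor and channel genes changed in both directions. Of 22 glutamate receptor genes, 4 rose, 2 fell and 16 did not pass, and adjusted over the list alone 7 rose and 2 fell. Grik4 (0.72), Grin2d (0.69), Grik2 (0.55) and Gria4 (0.43) rose, and Grm2 (-0.60) and Grid1 (-0.34) fell. Of 11 GABA receptor genes, Gabra2 (0.84) and Gabra3 (0.43) rose, Gabrb2 fell (-0.74) and 8 did not pass; adjusted over the list alone 6 rose and 3 fell. Of 21 voltage-gated potassium channel genes, Kcnd3 (0.79) and Kcnd2 (0.52) rose, and Kcnc2 (-0.48), Kcnh7 (-0.38), Kcnh3 (-0.37) and Kcnh5 (-0.33) fell, while 15 did not pass; adjusted over the list alone 3 rose and 6 fell. These lists did not pass as sets by camera (adjusted p = 0.217, 0.200 and 0.302), while by fry the GABA receptor list was higher (adjusted p = 0.0461). The interneuron markers, with a median log2 difference of -0.19, were lower in the same arrays by camera, a call that was lost with an estimated correlation (adjusted p = 0.0802). With inferred sex as a covariate 2 potassium channel genes fell, and without control 1, 6 did. Each of the 4 potassium channel genes that fell lost its call without some single array: Kcnc2 without control 2 or 3 or mutant 1 or 4, Kcnh7 without control 3 or 4 or mutant 2 or 4, Kcnh3 without control 2 or 4 or mutant 2 or 3, and Kcnh5 without control 3 or 4 or mutant 1, 3 or 4 (adjusted p from 0.0512 to 0.0961). Grik2 lost its call without any 1 mutant (0.0542 to 0.0859), and Grid1 without mutant 2 (0.0506).

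Of 17 pan-neuronal and excitatory neuron genes, Snap25, a synaptic SNARE protein (10.08 ± 0.04 to 9.26 ± 0.17, SD, n = 4), Rbfox3, the NeuN antigen, and Slc17a6, a vesicular glutamate transporter, fell (log2 differences of -0.82, -0.63 and -0.51), Neurod6 rose (0.70) and 13 did not pass. Adjusted over the list alone 1 rose and 4 fell, and the set did not pass (adjusted p = 0.214). Of 33 activity-regulated genes, 4 rose, 2 fell and 27 did not pass, and adjusted over the list alone 6 rose and 4 fell. The phosphatase genes Dusp4 (0.93) and Dusp6 (0.57), Nr4a3 (0.64) and Rgs4 (0.46) rose, and Nr4a2 (-2.15) and Rgs2 (-0.42) fell; the set did not pass (adjusted p = 0.943). Rgs4 lost its call without control 1, 2 or 3 or mutant 1, 2 or 4 (adjusted p from 0.102 to 0.141).

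Of 22 markers of interneurons, cells that arise outside the Emx1 lineage, 3 fell, 1 rose and 18 did not pass, and adjusted over the list alone 9 fell and 2 rose. Npy (8.76 ± 0.35 to 7.14 ± 0.57, SD, n = 4), the homeobox gene Dlx1 (-0.46) and Nxph1 (-0.31) fell, and the chemokine receptor gene Ackr3 rose (0.65). The median log2 difference of the list was -0.19, 18 of 22 members lay below 0, and its mean in each of the 4 mutants was below that of every control. The set was lower with an adjusted p of 1.05e-05 (adjusted p = 0.0802 with an estimated correlation). Nxph1 lost its call without any 1 array other than control 1 (adjusted p from 0.0508 to 0.108) and with the mean of its probe sets (-0.18, adjusted p = 0.187).

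Of 22 endothelial and mural cell markers, Abcc9 fell (-0.32) and 21 did not pass, and adjusted over the list alone 2 fell; the set was lower (median -0.07, adjusted p = 0.00148, and adjusted p = 0.211 with an estimated correlation). None of the 18 meningeal fibroblast markers passed with limma, over all genes or adjusted over the list alone, although the set was lower by camera (median -0.16, adjusted p = 9.34e-04, and adjusted p = 0.361 with an estimated correlation); this call was lost without the dimmest 50% of genes (adjusted p = 0.118) and with fry (0.151). Abcc9 lost its call without any 1 array other than control 2 or mutant 3 (adjusted p from 0.0699 to 0.109). Without control 1, 13 upper-layer genes fell and 3 rose, 4 interneuron markers fell and 2 rose, 2 GABA receptor genes fell, 2 Cajal-Retzius markers fell and 1 rose, and 0 vascular markers changed.

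Among 10 Cajal-Retzius cell markers Reln fell and 9 did not pass (3 fell and 1 rose adjusted over the list alone), with the call of Reln lost without control 2, 3 or 4 or mutant 2 or 3 (adjusted p from 0.0702 to 0.102). Of 17 neural progenitor markers, Insm1 rose (0.82), Vim fell (-0.36) and 15 did not pass; adjusted over the list alone 2 rose and 1 fell. Vim lost its call without control 2 or 3 or mutant 2 or 4 (adjusted p from 0.0726 to 0.0814). Of 14 striatal neuron markers, Meis2 (1.24) and Rarb (0.74) rose and 12 did not pass, and adjusted over the list alone 3 rose; both encode transcription factors. Of 17 oligodendrocyte lineage markers Cnp rose (0.55), and of 17 markers of phagocytic microglia Lpl, a lipase gene that also stands in the upper-layer list, fell (-0.79), with the same counts adjusted over the list alone. None of 24 astrocyte markers and none of 22 microglia markers passed with limma on either count; without control 1, 1 astrocyte marker rose and 1 fell. The Cajal-Retzius (adjusted p = 0.288), progenitor (0.943), striatal (0.214), oligodendrocyte (0.627), phagocytic microglia (0.804), astrocyte (0.953) and microglia (0.943) lists did not pass as sets by camera, while by fry the striatal list was higher (adjusted p = 0.00609).

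**Figure D4:**
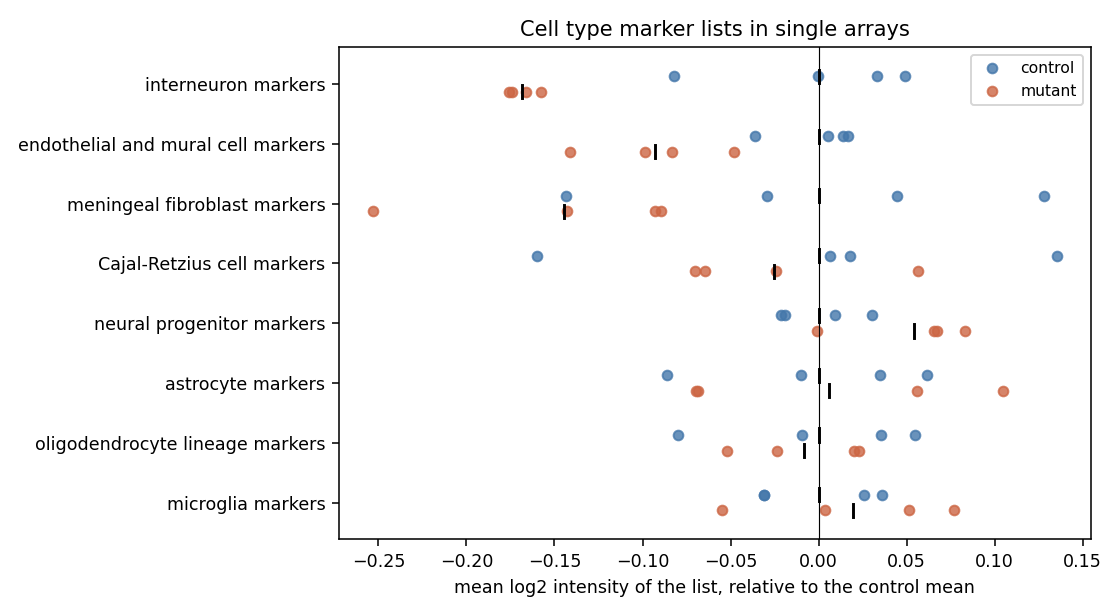
Mean log2 intensity of 8 cell type marker lists in each pup, relative to the control mean (dots, 4 controls and 4 mutants), with group means as bars. The 4 mutants lie below all 4 controls for the interneuron and for the endothelial and mural lists, while control and mutant values overlap for the meningeal, Cajal-Retzius, progenitor, astrocyte, oligodendrocyte and microglia lists.

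None of 33 cell cycle genes, 31 cytosolic ribosomal protein genes, 4 adult globin and red cell genes or 4 embryonic globin genes passed with limma, over all genes or adjusted over the list alone. Of 37 mitochondrial respiratory chain genes, Ndufa4 rose (0.35, adjusted p = 0.0456) and 36 did not pass, against 0 adjusted over the list alone; its call was lost without any 1 array other than mutant 2 (adjusted p from 0.0589 to 0.126). As sets the cell cycle (adjusted p = 0.804), ribosomal (0.943), adult globin (0.943), embryonic globin (0.489) and mitochondrial (0.217) lists did not pass. In all, camera called 7 of the 33 lists, 1 higher and 6 lower, fry called 10 (6 of these 7 with the cadherin, p53 target, GABA receptor and striatal lists), and camera with an estimated correlation called 0, with 4 at an unadjusted p under 0.05. For the cadherin, anti-apoptotic, other guidance, astrocyte and adult globin lists, which did not pass by camera, the sign of the set test differed from that of the median or the mean.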

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

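The comparison of single samples with the rest of their group was fixed before the data were examined. In the pattern weighed here, the tests of clock genes and of glucocorticoid targets were fixed after some values had been seen. The falls of Nr1d1 and Klf9 and the rise of Bhlhe40 were known, while the values of the other genes had not been looked at.

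Among 336 groups of 4 values, 19 held a pup that stood apart from the other 3 by Dixon's criterion, against 16.8 by chance, since about 1 group in 20 is marked with no cause. Control 1 was marked 6 times. It read 8.57 for Nr1d1 (other controls 8.10 to 8.18), 5.46 for Avpr1a (6.58 to 6.76), 8.29 for Ldb2 (9.58 to 9.74), 4.11 for Sema3d (4.50 to 4.51), 6.38 for Slit2 (7.23 to 7.28) and 6.83 for Osbpl3 (6.44 to 6.47). Control 2 read 5.68 for Rrm2b (6.06 to 6.13), with a mean over the areal patterning list of 8.33 (8.21 in the others), and control 4 read 7.57 for Chrm1 (7.14 to 7.22). Mutant 1 read 8.57 for Flrt3 (other mutants 8.05 to 8.12) and 6.35 for Nr4a3 (5.86 to 5.92). Mutant 2 read 5.99 for Bid (6.16 to 6.19) and 8.41 for Slc17a6 (8.15 to 8.19). Mutant 3 read 10.02 for Gabrb2 (9.75 to 9.78), with a mean over the semaphorin, plexin and neuropilin list of 7.37 (7.35 in the others). Mutant 4 read 6.31 for Rrm2b (6.49 to 6.51), 9.57 for Kcnd2 (9.74 to 9.76), 7.29 for Efnb1 (7.59 to 7.64) and 6.75 for Klhl13 (6.89 to 6.92).

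Nr1d1 and Klf9 (-1.22, adjusted p = 3.76e-06) fell while Bhlhe40 rose, and all 3 are genes with daily rhythms or hormone responses in many tissues. Lower glucocorticoid exposure of the mutant pups, as a common fall of targets by 0.3, is argued against: 15 other targets averaged -0.0258 (95% exact permutation interval -0.111 to 0.0742), and the 12 of them above the floor averaged -0.0302 (-0.125 to 0.0548). Of these 12, Sgk1 fell (-0.57) and Ddit4 rose (0.55), a call that was lost without control 1 or 4 or mutant 2, 3 or 4 (adjusted p from 0.0501 to 0.0974). A different time of day at dissection stays open: 8 clock genes in phase with Nr1d1 had a median of -0.19 (interval -0.42 to -0.06, which spans the -0.3 set beforehand), and Nr1d2 (-0.76), Dbp (-0.64) and Hlf (-0.60) fell, but Per2 (0.05, adjusted p = 0.896) and Per3 (-0.02, adjusted p = 0.953) did not pass, nor did Arntl (0.00), which peaks at the opposite phase. Times of dissection are not among the labels used here, and the hypothesis that loss of Bcl11a may lower Nr1d1 and related genes directly was not tested.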

How the results depend on the processing

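The tests on all probe sets and with inferred sex as a covariate were added after seeing the data. The direction and call of Bcl11a, Bcl6 and Sema3c held in all 54 alternative values, and without single arrays their differences ranged from -1.89 to -1.73, from -1.92 to -1.74 and from 1.45 to 1.48. The count of 827 changed genes moved beyond 1.5 times without variance moderation (249), with a minimum of 1.5-fold (280) and over all 35556 probe sets (518, where more tests are adjusted for); the cause of the first was not tested. It ranged from 584 without mutant 2 to 814 without control 1, which shared 711, and was 680 with sex as a covariate and 1113 at an adjusted p under 0.1. The count of 7 lists became 0 with an estimated correlation, 10 with fry, and 6 to 9 without single arrays. Of 2368 alternative values of the 132 other named genes, 2157 kept the call, 211 lost it and 0 reversed; 68 genes lost it at least once and 24 did so without a single array. With equal array medians the calls lost were those of Hey2, Grik2, Ndufa4, Sema5a, Rgs4, Osbpl10, Klhl13 and Ddit4 (adjusted p from 0.0536 to 0.102), and with the mean of a gene's probe sets those of Nxph1 (-0.18, adjusted p = 0.187) and Sema5a (0.0506). Replicate numbers were not taken to pair the pups, since nothing in the labels says so and not every correlation between the deviations of same-numbered pups exceeded 0.1 (0.109, 0.0558, 0.295 and 0.149); 6 of 8 pups correlated best with their own number, a hint of pairing from the data alone. With the replicate number as a block 987 genes passed, 789 of them shared, and 7 lists, and of the named genes Ndufa4, Osbpl10 and Klhl13 lost the call. Readings at or below the empirical floor of 4.31, which the means of 6290 genes did not exceed, may be background.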

Other observations

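Genes outside the fixed lists were named in this part after their values were seen, while the test of families was fixed before its result. The tests of extra deep-layer tissue as the whole cause, of dilution by excitatory neurons and of other splits for the gene count were chosen after the result was seen.

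Beyond the fixed lists, members of several gene families changed. The muscarinic acetylcholine receptor genes Chrm3 (0.89, adjusted p = 3.83e-05) and Chrm2 (0.59, adjusted p = 0.0107) rose while Chrm1 fell (-0.44, adjusted p = 0.0125). Among cation channels of the Trpc family, Trpc5 rose from 7.64 ± 0.14 to 8.89 ± 0.17 (SD, n = 4) and Trpc7 rose (1.07), while Trpc4 fell (-0.51). Of the contactins, Cntn6, Cntn3 (-0.83) and Cntn4 (-0.40) fell and Cntn5 rose (0.87). The kelch-like genes Klhl1 (-1.21), Klhl4 (-1.04) and Klhl32 (-0.86) fell and Klhl29 (0.37) and Klhl13 (0.26) rose, and Klhl13 lost its call without any 1 array other than mutant 4 (adjusted p from 0.0634 to 0.142). Dusp26 (0.62) and Dusp15 (0.43) rose with Dusp4 and Dusp6, all of which encode phosphatases, and Dusp15 lost its call without mutant 2 (adjusted p = 0.0589). Wnt7b rose (1.31, adjusted p = 0.00365), as did the Wnt enhancer Rspo2; with an intensity trend and robust variances the call of Wnt7b was lost (adjusted p = 0.0697).

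It was tested whether families of surface and guidance genes were over-represented among the changed genes, by grouping symbols with the same prefix. Of 120 families with at least 10 members, 2 passed a one-sided Fisher's exact test against 10350 background genes, of which 744 had changed. Of 13 Cdh genes, 6 had changed where 0.93 were expected (adjusted p = 0.018), 5 falling and 1 rising. The riser, Cdh13, lost its call without mutant 2, 3 or 4 (adjusted p from 0.055 to 0.0707). Cdh12, Cdh6 and Cdh13 also stand in the fixed cadherin list counted above, so this result is not separate from those calls. That list did not pass as a set by camera (adjusted p = 0.0582) but was lower by fry (adjusted p = 0.00435). Fisher's exact test also takes genes as independent. Of 10 Osbpl genes, which encode oxysterol-binding proteins of lipid transport, 5 had changed where 0.72 were expected (adjusted p = 0.0211). Osbpl1a (-0.51), Osbpl3 (-0.44) and Osbpl9 (-0.35) fell and Osbpl6 (0.36) and Osbpl10 (0.31) rose; Osbpl3 lost its call without mutant 2 or 3 (adjusted p = 0.0577 and 0.0609) and Osbpl10 without control 1, 2, 3 or 4 or mutant 1 or 3 (0.0525 to 0.0944). Semaphorins (4 of 16, adjusted p = 0.481), Dusp genes (4 of 16, adjusted p = 0.481) and Klhl genes (5 of 26, adjusted p = 0.528) did not pass, and the Chrm, Trpc and Cntn families, with fewer than 10 members each among the background genes, were not tested.

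By camera the upper-layer list was lower and the deep-layer list higher, each call lost with an estimated correlation (adjusted p = 0.329). These shifts could come from deeper dissection in mutants or from a change in the neurons themselves. Extra tissue of layers V and VI would raise the core regulators of these layers together, but the mean difference of 6 of them was 0.21 (95% exact permutation interval 0.08 to 0.49), with the upper end just under the 0.5 set beforehand. Such tissue alone does not account for all changes in the deep-layer and subplate lists, since 4 of their genes, Cntn6, Ntsr1, Ephb1 (-0.77, and -0.40 with the mean of its probe sets) and Nr4a2, fell. The falls were known when this question was put. The call of Nr4a2 was lost with an intensity trend and robust variances (adjusted p = 0.0705). Without variance moderation those of Nr4a2 (adjusted p = 0.137) and Cntn6 (0.084) were lost, while Ntsr1 and Ephb1 kept theirs. These falls do not show what raised the other deep-layer genes or lowered the upper-layer ones. A smaller share of deep tissue stays open, as the interval lies above 0, although none of the 6 passed and Fezf2 (0.80) stood far above their median of 0.11. A change of layer identity in mutant neurons is a hypothesis that these data do not test.

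The interneuron, vascular and meningeal lists were lower by camera, with each call lost with an estimated correlation (adjusted p = 0.0802, 0.211 and 0.361) and the meningeal call lost with fry (0.151). Control 1 is not the cause, since without it the list median closest to 0 was still -0.079. Dilution by more excitatory neurons would lower glial lists alike, but astrocyte, oligodendrocyte and microglia lists stood above the interneuron list by 0.174 (95% exact permutation interval 0.024 to 0.304). The list values had been seen when this comparison was chosen, so the gap describes them and is not an independent test. Much of the glia is of the Emx1 lineage too, so this gap counts against an even dilution only if mutant glia kept their markers. The vascular and meningeal lists were not part of this comparison. Fewer interneurons in the mutant layers stays open: 8 core interneuron genes averaged -0.196 (interval -0.281 to -0.121), but all 8 belong to the list that prompted the question, 7 lay below 0, among them Lhx6 (control mean 8.01) and Gad1 (7.41), of which only Dlx1 (-0.46, control mean 8.74) passed, and Dlx6 (0.09, adjusted p = 0.765) lay above 0. Lower expression per cell was not told from fewer cells, and the vascular and meningeal values stay unexplained.

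Of the 35 splits of the 8 arrays into 4 and 4 only 1, the real one, gave 827 changed genes, and the highest other gave 0. This is the smallest share that 35 splits can give. Every other split mixes the genotypes, so a genotype difference adds to its spread and holds its count down. The gene count thus stands apart from the other splits, without excluding chance. Chance cannot be excluded for the count of lists either: 3 of the 35 splits called at least the real 7, and the highest other called 13. Unequal sex of the groups is not the cause of the gene count, as 79.7% of the changed genes still passed with inferred sex as a covariate.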
